A study of Bos taurus with 6 samples.

How the data were processed

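Bovine fibrocytes cultured in fibroblast medium (FbM) or fibrocyte medium (FcM) were profiled by RNA sequencing in 6 libraries, 3 per medium. Per the labels' protocols, messenger RNA was selected from total RNA with poly-T beads, and cDNA was made with random hexamer primers. Each library was assigned to its medium by its title. The protocol writes the short form of the fibrocyte medium in another way than the titles do, and the titles were taken to name the medium by its initials.

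The authors deposited, for each library, a table of read counts per gene with 4 summary lines followed by 36075 Ensembl gene IDs, in the layout that STAR writes. Per the submitters' processing notes the tools were STAR and edgeR and the genome build was ARS-UCD1.2, and their versions are not given in the sources used here. Such a table holds counts without regard to strand and counts for each strand. The sense column held between 50.5% and 50.8% of the reads in the stranded columns, so the unstranded column was used, by a rule fixed before the data were examined that asked for over 90% in 1 stranded column otherwise. Without strand, reads of overlapping and antisense genes cannot be told apart. The line for reads that map to several places is 0 in all 6 libraries, so such reads do not enter the counts, and genes with near-identical copies are uncertain. The summary lines were left out of library sizes and tests. Reads listed in no feature, which can include reads in introns, were 12.9% to 21.7% of the aligned reads listed. Ambiguous reads were 4.58% to 5.69%.

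Depth was 15925280 to 19149516 gene reads per library. A gene with 0 reads in a library can have a level of up to 0.157 to 0.188 CPM, taken as 3 reads. Of the 36075 genes, 12955 had 0 reads in every library. No libraries held identical values. Over genes with higher counts, the median squared difference between the scaled counts of any pair was at least 13.7 times that of Poisson sampling.

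From the deposited counts, CPM with TMM scaling were computed for levels, and log2 CPM with a prior count of 2 for the principal components, correlations and positions. The media were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a false discovery rate of 0.05 over 14211 genes. The design, the alternatives and the rule for named genes were fixed before the data were examined. Library measures were compared with an exact two-sided permutation test in SciPy 1.17.1. On simulated counts for the same 14211 genes in 6 libraries, with 50 genes changed at each size, the test recovered 6% of 2-fold, 52% of 4-fold, 98% of 16-fold and 100% of 64-fold changes, and called 2 of 14011 unchanged genes. Changes near 2-fold were thus mostly missed in the simulation. It gave both media the same spread between libraries, with no library apart and no link between libraries of the same number. It also drew each gene with the average spread of genes at its level, without a spread of its own. The measured spread was larger in FcM than in FbM, so these rates may not carry over to the real libraries.

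Whether the numbers in the titles pair the libraries was checked from the deviations of each library from its medium's mean log2 CPM, since the labels do not state it. These correlated across genes at 0.34 for FbM_1962 with FcM_1962, 0.40 for FbM_1944 with FcM_1944 and 0.25 for FbM_1951 with FcM_1951, and 6 of 6 libraries correlated best with the library of their own number. Deviations within a medium of 3 libraries are tied to each other, so the 6 matches are not independent. With each pair above 0.1 the numbers were taken as a possible pairing, which this check cannot establish with 3 libraries per medium. The main test and the permutation tests did not use this pairing, and the blocked fit is given as an alternative. In the blocked edgeR fit 0 genes were called for the number, with 1043 at an unadjusted p under 0.05; no other tool was run for the number.

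The alternatives were size factors as in DESeq2, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, no filter, a filter of 1 CPM in 3 libraries, the number as a block, the sense column, a test against a 2-fold change, and leaving out each library or both libraries of each number. Others were added after the data were examined. They were removal of the 20 most abundant genes, voom with quality weights, the block without FcM_1962, a robust edgeR fit, leave-one-out fits on the genes tested in all 6 libraries, and another rule for genes present in 1 medium.

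The rule for named genes took the largest fold changes in each direction among genes past the false discovery rate, with a mean log2 CPM of at least 1 and all libraries of one medium above those of the other. It also asked for a gene symbol and named fixed genes and list members by symbol. The files pair no symbols with the gene IDs. Of the 37063 rows of the reference gene table used (assembly ARS-UCD2.0) 0 held an Ensembl ID, so no ID could be matched to a symbol. The symbol condition was therefore dropped and 2 IDs per direction are given. The 37 gene lists fixed for inflammation, proliferation, the additives and cell types, with their set tests and the levels of markers of other cell types, were not analysed here.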

Results

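Gene expression was measured by RNA sequencing in bovine (Bos taurus) fibrocytes grown in 2 culture media. Fibrocytes are cells that circulate in blood and combine features of leukocytes with those of fibroblasts, and here they were grown from the nucleated cells of blood on dishes coated with 0.1% gelatin. The fibroblast medium (FbM) held high-glucose DMEM, 20% fetal bovine serum, antibiotics and non-essential amino acids. The fibrocyte medium (FcM) held the same components and 6 additives. These were 10 nM dexamethasone, a synthetic glucocorticoid, 0.1 mM ascorbic acid 2-phosphate, a stable form of vitamin C, and the growth factors PDGF-BB and EGF at 10 ng/mL each. The other 2 were small-molecule kinase inhibitors. A83-01, at 0.5 μM, blocks type I receptors of the TGF-β family, and CHIR99021, at 1.5 μM, blocks GSK-3 and so activates Wnt signalling. There were 3 libraries per medium, FbM_1962, FbM_1944 and FbM_1951 against FcM_1962, FcM_1944 and FcM_1951, named here by their titles, in which the 2 media share 3 numbers. The labels do not say what these numbers identify, nor that the cultures came from separate animals, so the p-values measure the spread between these samples.

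Reads assigned to genes came to 16143812, 17033279 and 19149516 in FbM_1962, FbM_1944 and FbM_1951. They came to 16408604, 16227618 and 15925280 in FcM_1962, FcM_1944 and FcM_1951. The reads listed as unmapped were 14.0% ± 2.23 of all reads in FbM and 18.2% ± 1.22 in FcM (SD, n = 3 each). Every FcM library lay above every FbM library, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow (0.35 after Benjamini-Hochberg adjustment over 7 library measures). It is not stated where reads that map to several places were listed, so the unmapped line may hold some of them. The 100 most abundant genes of a library took 28.1% ± 0.987 of its gene reads in FbM and 24.1% ± 1.65 in FcM (SD, n = 3 each), also without overlap (exact permutation p = 0.1, adjusted 0.35). Depth overlapped between the media (exact permutation p = 0.3, adjusted 0.42).

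The comparison of the media bears on the question named in the study's design, which culture conditions go with a lower inflammatory response and with proliferation. The files pair no gene names with their Ensembl gene IDs, so the genes of inflammation and of proliferation were not analysed here, and the genes are described below by direction, level and size of change.

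Among the genes that passed the edgeR test with all 6 libraries, those lower in FcM outnumbered those higher in FcM, a balance that turned under the DESeq2 test, and included transcripts at 100 CPM or more in every FbM library and under 10 CPM in every FcM library. Of 14211 genes tested, 495 differed between the media at a false discovery rate of 0.05 (edgeR quasi-likelihood test), of which 338 were lower and 157 higher in FcM. The median log2 fold change was -3.42 for the lower genes and 2.99 for the higher genes. Among the lower genes the median of the mean level was 42.2 CPM (read counts scaled to library size) in FbM and 3.43 CPM in FcM. Among the higher genes it was 5.79 CPM in FbM and 40.9 CPM in FcM. Fitted changes exceeded 16-fold for 133 lower and 42 higher genes. These medians and counts were the same with the 13 lower and 4 higher genes that had 0 reads in 1 medium set at the bound that 3 reads give. All 495 genes had the 3 libraries of one medium above the 3 of the other, a pattern that chance gives for 10% of genes and that 32.8% of all tested genes showed.

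These counts and the balance of directions depended on the test and on the libraries entered. Which genes passed also depended on the pairing by number. With the number as a block, edgeR passed 427 genes, 156 higher and 271 lower in FcM. Of the 495 genes, 283 kept their call and 212 lost it. With the same 6 libraries the DESeq2 Wald test passed 2769 genes, 1619 higher and 1150 lower in FcM (58.5% higher), and limma-voom with library quality weights, chosen after the data were examined, passed 2295 higher and 2353 lower. In edgeR, 31.7% of the 495 genes were higher. Without FcM_1962, 4394 genes passed in edgeR, 2576 higher and 1818 lower in FcM (58.6% higher), and all 495 genes were among them. Without FbM_1962, FbM_1944 or FbM_1951 the counts were 10, 5 and 2, without FcM_1951 the count was 3, and without FcM_1944 it was 222.

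**Figure D1:**
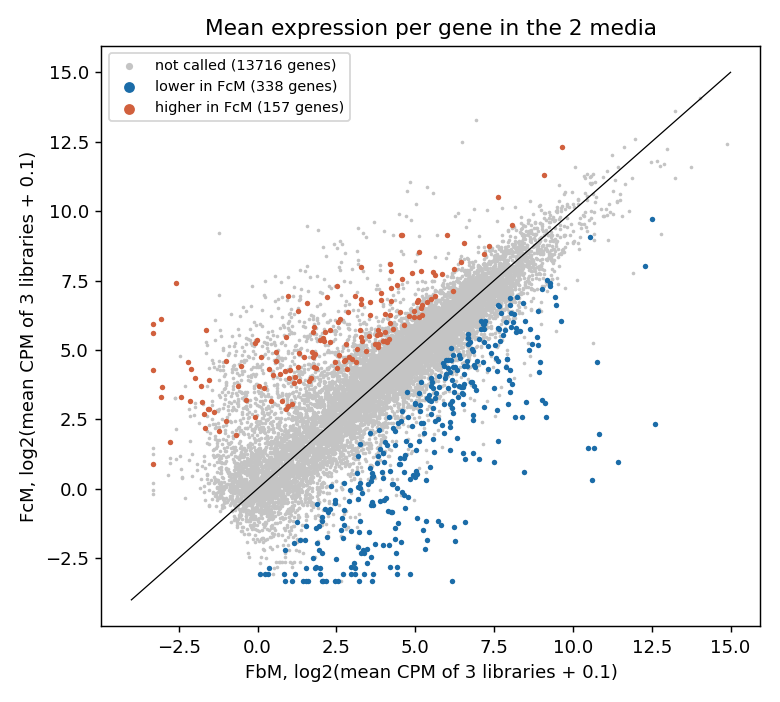
Mean expression of each of the 14211 tested genes in FbM (horizontal axis) and FcM (vertical axis), as log2 of the mean CPM of 3 libraries plus 0.1. Blue points are the 338 genes lower in FcM, red points the 157 genes higher in FcM and grey points the genes that did not pass the edgeR test at a false discovery rate of 0.05. The diagonal marks equal levels.

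The genes lower in FcM together took 5.81% ± 0.942 of the gene reads in FbM and 0.705% ± 0.164 in FcM (SD, n = 3 each). The genes higher in FcM took 0.386% ± 0.0284 in FbM and 2.28% ± 0.313 in FcM (SD, n = 3 each). These genes were chosen on the same libraries, so the shares describe their weight in the transcriptome and are not a separate test.

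With all 6 libraries, genes that were abundant in each library of one medium and low in each library of the other were mostly FbM genes. There were 14 genes at 100 CPM or more in every FbM library and under 10 CPM in every FcM library, and 0 genes with the reverse pattern (25 and 31 without FcM_1962). None of the 14 was under 1 CPM in every FcM library, and their highest level in FcM was 9.87 CPM, with a median of 5.15 CPM in FcM_1962. The 14 genes summed to 17571 ± 4836 CPM in FbM and 47.9 ± 23.5 CPM in FcM (SD, n = 3 each), a ratio of 367. Of these, 4 genes stood at 1000 CPM or more in every FbM library, and they summed to 12385 ± 3441 CPM in FbM and 11.8 ± 5.14 CPM in FcM (SD, n = 3 each). None stood at 1000 CPM or more in FcM with under 10 CPM in FbM, with all libraries or without FcM_1962. At lower levels, 28 genes stood at 10 CPM or more in every FbM library and under 1 CPM in every FcM library, and 7 genes showed the reverse. The 28 genes summed to 978 ± 157 CPM in FbM and 9.14 ± 2.82 CPM in FcM, and the 7 genes to 1.40 ± 0.417 CPM in FbM and 402 ± 256 CPM in FcM (SD, n = 3 each). The 7 genes summed to 694 CPM in FcM_1962, and their mean sum in FcM was 255 CPM without it. Every gene of these groups passed the edgeR test. The other 9 splits of the 6 libraries into 3 and 3 gave at most 6 genes at the bounds of 10 and 1 CPM, and at most 1 at the bounds of 100 and 10 CPM, with both directions added. Each of these splits puts FbM and FcM libraries on both sides. Genes that follow the medium cannot meet the bounds there, so these counts do not measure chance.

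The bounds for these groups were set after the data were examined, and the rule that every library must reach the upper bound replaced an earlier rule. Under the earlier rule the mean of a medium had to reach 10 CPM, with every library of the other medium under 1 CPM. It gave 45 genes for FbM and 65 for FcM, 110 in all, and another split of the libraries, with FbM_1962, FbM_1951 and FcM_1962 on one side, gave 146. Of the 45 and 65 genes, 43 and 15 passed the edgeR test. Without FcM_1962 the rule on every library gave 48 genes for FbM and 117 for FcM at 10 and 1 CPM, so the excess on the FbM side was not seen without that library.

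The 2 genes with the lowest and the 2 with the highest fitted fold changes, among 471 genes past the rule for named genes, each had 0 reads in 1 medium. ENSBTAG00000007302 stood at 71.9 ± 28.4 CPM in FbM (SD, n = 3) and had 0 reads in the FcM libraries, which puts it at least 1205-fold lower in FcM (edgeR adjusted p = 0.00987). ENSBTAG00000019066 stood at 12.2 ± 9.31 CPM in FbM (SD, n = 3) with 0 reads in FcM, at least 205-fold lower (edgeR adjusted p = 0.0456). Its FbM libraries spanned 2.09 to 20.4 CPM, and without FbM_1944 the bound was 136-fold. With the number in the title as a block its edgeR adjusted p was 0.0532, which ends the call, while the fitted log2 change was -10.66 against -10.68 without the block. Over 27 alternatives the adjusted p ranged from 3.67e-10 to 0.429. ENSBTAG00000001324 had 0 reads in FbM and stood at 61.6 ± 64.1 CPM in FcM (SD, n = 3), at least 1037-fold higher (edgeR adjusted p = 0.0333). Its FcM libraries spanned 19.1 to 135 CPM, and without FcM_1962, the highest, the bound was 417-fold. ENSBTAG00000004293 had 0 reads in FbM and stood at 48.8 ± 27.0 CPM in FcM (SD, n = 3), at least 821-fold higher (edgeR adjusted p = 0.0165). The bounds set the mean level in 1 medium against 3 reads over the 3 libraries of the other, about 0.0596 CPM in FcM and 0.0594 CPM in FbM, and cover counting error only. With the filter applied again, none of the 4 genes kept its call without FbM_1962, FbM_1944, FbM_1951 or FcM_1951 (edgeR adjusted p from 0.0514 to 0.181). The fitted log2 changes lay from -13.50 to -12.85 for ENSBTAG00000007302, from -11.22 to -10.11 for ENSBTAG00000019066, from 12.97 to 13.32 for ENSBTAG00000001324 and from 12.55 to 12.71 for ENSBTAG00000004293. With 0 reads in 1 medium, these fitted values lie beyond the bounds above, so they do not measure the size of the change. Ranking on fitted values favours such genes, so the named genes need not hold the largest changes. The 4 genes at 1000 CPM or more in every FbM library had a ratio of summed means of 1051, above the 205-fold bound of ENSBTAG00000019066. On the genes tested in all 6 libraries, ENSBTAG00000007302 kept its call without FbM_1944 (edgeR adjusted p = 0.0474) and without FbM_1951 (0.0420).

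The libraries of FbM resembled each other more closely than those of FcM, among which FcM_1962 stood apart. Spearman correlations across genes, which are not independent replicates, lay between 0.959 and 0.969 for the 3 pairs of FbM libraries. In FcM, FcM_1951 and FcM_1944 correlated at 0.951, while FcM_1962 correlated with FcM_1951 at 0.879 and with FcM_1944 at 0.806. FcM_1962 correlated with the FbM libraries at 0.915 to 0.931. The biological coefficient of variation estimated by edgeR was 0.350 in FbM and 0.590 in FcM. Without FcM_1962, the pair FcM_1951 and FcM_1944 gave 0.389, against 0.318 to 0.382 for the pairs of FbM libraries. The first principal component of log2 CPM held 65.9% of the variance and placed FcM_1962 at -29.3, FcM_1951 at 106, FcM_1944 at 155 and the FbM libraries from -91.1 to -56.2. The second held 16.9%.

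**Figure D2:**
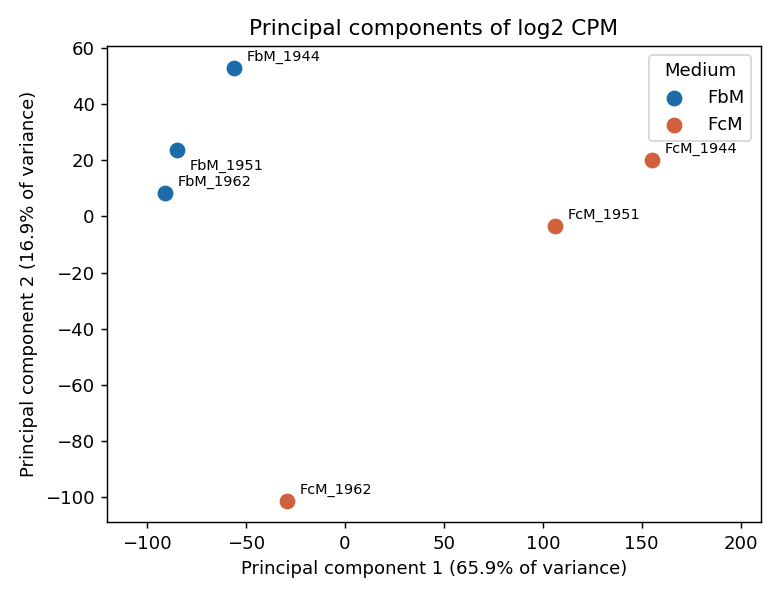
Principal components 1 and 2 of log2 CPM over the 14211 tested genes, 1 point per library, with blue for FbM and red for FcM; the axes give component scores. FcM_1962 stands at -29.3 on component 1, between the FbM libraries and the other 2 FcM libraries, and at -101 on component 2.

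The position of each library was also read from genes chosen without it. For each library, the 500 genes with the lowest p in an edgeR fit of the other 5 were taken from those also tested with all 6, and its log2 CPM was placed on a scale where 0 is the mean of the other medium and 1 the mean of the other 2 libraries of its own medium. The median position was 0.97, 1.00 and 0.89 for FbM_1962, FbM_1944 and FbM_1951, 0.99 for FcM_1951 and 1.13 for FcM_1944. For FcM_1962 it was 0.32. It was 0.65 over the 178 genes lower in FcM and 0.12 over the 322 genes higher in FcM. Of the 4394 genes called without FcM_1962, 3824 were also among the 14211 genes tested with all 6 libraries, and over these its median position was 0.41 for the 1786 lower genes, of which 58.3% were nearer the FbM mean, and 0.21 for the 2038 higher genes. The contrast between lower and higher genes was thus smaller over these 3824 genes than over the 500, and the other called genes were not placed. This measure was chosen after the position of FcM_1962 had been seen. The genes for the other 5 libraries were chosen in fits that held FcM_1962, so their positions are not a like-for-like baseline for its own.

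**Figure D3:**
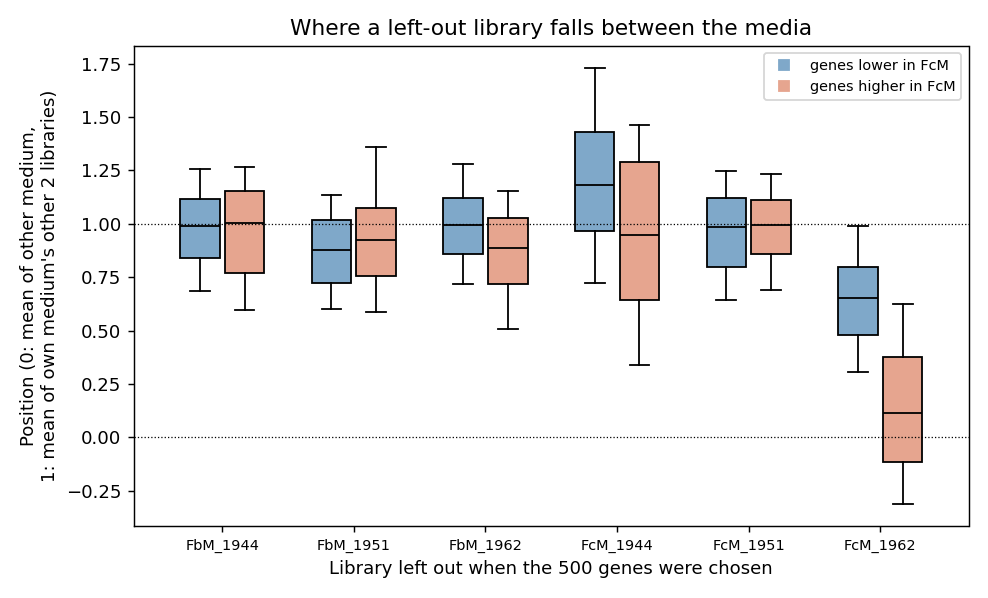
Position of each library between the media over 500 genes chosen without it, on a scale where 0 is the mean of the other medium and 1 the mean of the other 2 libraries of its own medium. Boxes span the quartiles with the median as a line and whiskers reach the 10th and 90th percentiles, blue for genes lower in FcM and red for genes higher in FcM; the medians of FcM_1962 are 0.65 and 0.12.

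The number of genes detected also varied most in FcM. After thinning to an equal depth of 15925280 reads, 17581 ± 340 genes had at least 1 read in FbM and 18752 ± 907 in FcM (SD, n = 3 each; exact two-sided permutation p = 0.2, adjusted 0.42). FcM_1951 and FcM_1944 had 19431 and 19104 genes, and FcM_1962 had 17722. Without thinning, the genes with at least 10 reads numbered 14062 ± 401 in FbM and 14297 ± 720 in FcM (SD, n = 3 each; exact permutation p = 0.7).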

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

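The added settings named in the methods were chosen after the data were examined. Against 495 genes, 2769 passed with the DESeq2 Wald test (1619 higher, 1150 lower, all 495 among them) and 171 in the test against a 2-fold change. Among the added settings, 4648 passed with voom quality weights, where FcM_1962 had the lowest weight (0.282), and 4879 with the block when FcM_1962 was left out. The cause of the difference between DESeq2 and edgeR was not tested. Under the other settings with all libraries the count was 401 (limma-voom) to 643 (no filter). The replicate block gave 427 genes, of which 283 were among the 495, so 212 genes lost their call; among the named genes it ended the call of ENSBTAG00000019066 and of no other. Size factors as in DESeq2 left 491 of the 495 genes called. No called gene changed sign under these settings or without any library, where it was tested. All 495 genes had the libraries of one medium above those of the other, so a change of sign was unlikely from the start.

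Leaving out libraries gave counts from 0 to 4394. Without FbM_1962, FbM_1944 or FbM_1951 the counts were 10, 5 and 2, and without FcM_1951, FcM_1944 or FcM_1962 they were 3, 222 and 4394. Without both libraries that share a number they were 19 (FbM_1944 and FcM_1944), 0 (FbM_1951 and FcM_1951) and 2921 (FbM_1962 and FcM_1962). Beside the 0, 1430 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 856. The filter was applied again to the libraries left. On the 14211 genes tested in all 6 libraries, the counts in the same order were instead 41, 18 and 79 without an FbM library and 3, 232 and 3788 without an FcM library, so the low counts without an FbM library depend in part on the filter. The rest of the cause was not tested. DESeq2 called from 1582 to 5566 genes when 1 library was left out.

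The named genes kept their sign in 27 alternatives each, an outcome that their 0 reads in 1 medium fixed beforehand. ENSBTAG00000007302 lost its call in 7 of them, ENSBTAG00000004293 in 9, ENSBTAG00000001324 in 12 and ENSBTAG00000019066 in 16. The counts of genes at 10 CPM or more in every library of one medium and under 1 CPM in every library of the other were 23 to 34 for FbM and 7 to 10 for FcM under the scalings, filters, sense column, removal of the 20 most abundant genes and most leave-outs. The exceptions were 48 and 117 without FcM_1962, 53 and 126 without FbM_1962 and FcM_1962, and 45 and 65 by the rule on the mean. The planned set tests of the gene lists, with their alternatives, and the removal of mitochondrially encoded genes were not run, since the gene IDs were not paired with names.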

Other observations

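All tests here were chosen after the results they bear on had been seen. The genes that differed lay at all levels of expression. Of the 91 tested genes with a mean of 1000 CPM or more over the 6 libraries, 5 were lower and 2 higher in FcM. From 100 to 1000 CPM, 66 of 2081 genes were lower and 21 higher, and from 10 to 100 CPM 155 of 7255 were lower and 97 higher. From 1 to 10 CPM, 105 of 4011 genes were lower and 36 higher, and under 1 CPM 7 of 773 were lower and 1 higher.

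The edgeR count of 495 genes was the highest of the 10 splits of the 6 libraries into 3 and 3, and 1 split, the real one, reached it. The other 9 splits called at most 0 genes in edgeR, with up to 1859 at an unadjusted p under 0.05, and up to 976 in DESeq2. Each of them puts FbM and FcM libraries together on both sides. The difference between the media then adds to the spread within each side, so few edgeR calls were likely from the start. With 10 splits no share under 0.1 can be had, so the splits are too few for a statement on chance. The 3 other splits that part all 3 numbers called 0 genes in edgeR. In these, up to 1033 genes had an unadjusted p under 0.05 and up to 502 passed in DESeq2.

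FcM_1962 lay nearer the FbM libraries than the other 2 FcM libraries did. A mixture of RNA from the 2 kinds of culture predicts that genes specific to each side add up to about 100% of their levels, but the medians in FcM_1962 added up to 2.87%, which is 2.66% of the FbM level over 20 genes high in FbM and 0.209% of the FcM level over 22 genes high in the other 2 FcM libraries. This argues against a mixture with cells like those of the other 2 FcM libraries. It cannot speak to a mixture with an FcM culture in which the 22 genes are low. The 2.66%, with a maximum of 14.5%, also argues against an FbM library under the wrong label, and depth argues against too few reads, at 1.03 times the reads of the shallower of the other 2. A difference in a source that FbM_1962 and FcM_1962 may share, which the labels do not state, may underlie the position. Their deviations correlated at 0.34 across genes, between 0.40 for FbM_1944 with FcM_1944 and 0.25 for FbM_1951 with FcM_1951. Deviations within a medium are tied to each other, at -0.875 for FcM_1944 with FcM_1962 and -0.653 for FcM_1951 with FcM_1962. The 0.40 and 0.25 are thus not a separate baseline, and the comparison cannot decide on a shared source. With 1 library such a difference in source cannot be told apart from a difference in culture or preparation.

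FcM_1951 and FcM_1944 had more genes with a read than any FbM library. Depth does not account for this, since after thinning to an equal depth the lower of the 2 still exceeded the highest FbM library by 1148.5 genes, against a range of 17292 to 17956 in FbM. Without thinning, FcM_1951 had 15015 genes with at least 10 reads, above the FbM range of 13652 to 14454, but FcM_1944 had 14301, inside it. The excess in FcM_1944 thus lay in genes with 1 to 9 reads, 4827 against 2898 to 4317 in FbM. Background reads from genomic or unspliced RNA would raise the share of aligned reads listed in no feature. In FcM_1944 that share was 12.9%, below the FbM range of 17.9% to 21.7%, which argues against such background there. In FcM_1951 it was 19.1%, inside that range, and although each FcM library lay below the FbM library of its number (21.7% in FbM_1951, 18.6% in FbM_1944, and 17.9% against 15.4% for FbM_1962 and FcM_1962), which goes against more background, the fall in FcM_1951 was smaller than the range of the FbM libraries, so background there cannot be told apart from expression of more genes. Expression of more genes, or more kinds of cells in these cultures, may also be at work and was not tested, since the gene IDs were not paired with names.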
